A study of Mus musculus with 8 samples.

How the data were processed

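RNA was measured by sequencing in bone fractions enriched for osteocytes, the cells embedded in mineralized bone matrix, from the frontal bone, the parietal bone and the femur of C57BL/6 mice aged 12 weeks, per the labels. There were 3 femur, 3 frontal and 2 parietal libraries. Total RNA was made into libraries with the Nextera XT method and read as paired ends, per the labels' protocols. Libraries are named here by bone and by the number in their description (1, 2 or 4), which differs from the running number in some titles. Nothing in the labels says whether the libraries came from separate animals or from pools, so p-values measure only the spread between these libraries, which may in part be technical.

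The authors deposited a table of raw counts per gene, a filtered copy of those counts and a table of scaled values. The deposited raw counts were whole numbers with 43438 rows, of which 92 were spike-in controls and 43346 were genes. The filtered table held 23065 rows with the same counts, and 108 of its rows were 0 in all 8 libraries, so its filter was not made on these 8 libraries alone. The third deposited table held a normalized signal, a scaled CPM (read counts relative to a scaled library total) with TMM (trimmed mean of M values) in its name, whose columns summed to different totals. STAR 2.5.2a, DESeq2, edgeR and limma, and the builds GRCm38.p3 and mm10, are named in the submitters' processing notes. Which of these made which table, the counting tool, its strand setting and the annotation are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart by these counts, and near-identical copies (the Bglap, globin, histone, Xlr, Ly6 and Hspa1 families, and processed copies of ribosomal protein genes) have uncertain values.

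Symbols were found for 42462 of the 43346 genes. The 884 genes without a symbol held 0.114 to 0.151% of each library's counts and stayed in the tests. Positions are those of GENCODE M21 on GRCm38, the assembly of the submitters' build. The annotation release behind the counts may differ from it. Spike-ins were left out of library sizes and tests. Library totals over genes ran from 6259229 to 13461622 counts. A group without any count for a gene was set at a floor of 3 counts over that group's total, and folds against it are lower bounds. For groups with 1 to 3 counts the ratio is given with an exact 95% Poisson interval. Both cover counting error only.

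Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (15511 genes), libraries were scaled by TMM, and a robust quasi-likelihood model with the 3 bones as groups was fitted to all 8 libraries, so that the spread is estimated over all bones, since 2 parietal libraries alone leave 1 degree of freedom. It had 5 residual degrees of freedom and a biological coefficient of variation of 18.6%. The comparisons were calvaria (the mean of frontal and parietal) against femur, frontal against femur, parietal against femur, and frontal against parietal. p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called changed at an adjusted p under 0.05. Standard errors (SE) were derived from the fold change and its F statistic. CPM values are edgeR's, on the TMM scale.

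Gene lists for bone cells, signalling pathways, body position, other cell types and cell states were fixed before the data were examined, 44 in all. The 43 lists with at least 5 tested members were tested with limma 3.58.1's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry were run beside it. Member counts are given by the adjustment over all genes, and adjusted over the list alone where that differs. Named genes followed a rule fixed at the same time. It took, per comparison, the 8 genes with the largest log2 fold change in each direction among changed genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups compared, leaving out predicted gene models, immunoglobulin and T cell receptor segments and pseudogenes. It also took the 4 members with the smallest p of each list discussed, and Sost, Dmp1, Mepe, Phex and Fgf23 throughout. Members that stand outside it, because they moved against their list or did not pass, were chosen after their values were seen and are given as such. Some members of the lists are not reported here.

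Shares of counts in 5 lists were compared between 5 calvarial and 3 femur libraries by an exact two-sided permutation test over 56 splits, with a smallest possible p of 0.0179, which takes the libraries as exchangeable. No pair of libraries of a bone agreed within sampling noise (chi-square per degree of freedom of 7.16 or more). On simulated counts with 200 changed genes, the edgeR step recovered 93.9% of 4-fold and 54.6% of 2-fold changes for calvaria against femur. For frontal against parietal it recovered 84.5% and 45.4%, and 9.3% and 6.0% of calls were false. Far more genes were called in every real comparison, so these rates need not hold there. The list step called the 1 raised list and 0 of 20 unchanged lists in each comparison. Simulated genes varied independently, so this cannot show how often the list step calls unchanged lists whose genes vary together.

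Alternatives fixed at the same time were DESeq2 size factors, library size only, other filters, DESeq2 1.42.0, limma-voom, a replicate block, other thresholds, fits on fewer genes or libraries, and leaving out each library. A 2-group fit, scaling to the osteocyte list, leaving out all lists of other cell types, and removal of a trend with transcript length and GC content (known for 15435 of the 15511 tested genes) were added after seeing the data, as were shares without the list member that differs most.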

Results

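Gene expression was measured by RNA sequencing in 3 femur, 3 frontal and 2 parietal libraries of osteocyte-enriched bone fractions of mice, to examine how the transcriptome of osteocytes differs between flat bones of the skull vault and a long bone. Total gene counts were 6259229, 11069689 and 8780206 in femur libraries 1, 2 and 4. They were 8001302, 9641928 and 7025433 in frontal libraries 1, 2 and 4, and 13461622 and 10190495 in parietal libraries 2 and 4.

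Femur libraries stood apart from calvarial ones by correlation, while the correlations within a bone and between frontal and parietal bone overlapped. The mean Spearman correlation across genes was 0.98 ± 0.005 (SD) over the 7 pairs of libraries from 1 bone. It was 0.966 ± 0.008 over the 6 frontal-parietal pairs and 0.873 ± 0.020 over the 15 femur-calvaria pairs. The first principal component held 70.2% of the variance and placed the 3 femur libraries apart from the 5 calvarial ones. The second held 10.7%, with both parietal libraries above all 3 frontal libraries.

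**Figure D1:**
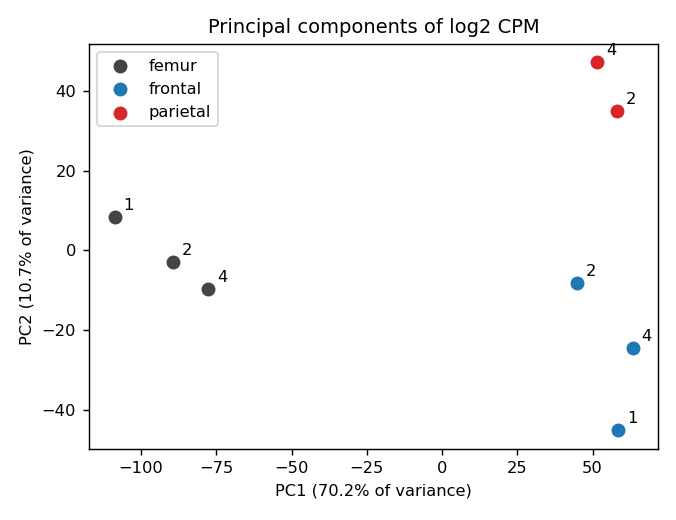
Principal components of log2 CPM, with 1 point per library, coloured by bone and numbered by library. The horizontal axis, with 70.2% of the variance, parts femur from calvaria, and the vertical axis, with 10.7%, parts frontal from parietal libraries.

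The fractions differed in what else they held. Genes of the osteocyte list took 4.11 ± 1.34% (SD, n = 3) of counts in femur, 0.232 ± 0.0294% (n = 3) in frontal and 0.287 ± 0.0044% (n = 2) in parietal bone. Most of this gap was Dmp1, at 3.35 ± 1.25% in femur and 0.054 ± 0.0099% in calvaria (n = 5). The other members took 0.760 ± 0.123% and 0.20 ± 0.0295%. Erythroid genes took 2.19 ± 0.89% in femur and 8.79 ± 1.92% (n = 5) in calvaria, and granulocyte genes 3.46 ± 1.53% and 8.77 ± 0.909%. Both were higher in all 5 calvarial libraries than in any femur library (exact permutation p = 0.0179 each, 0.0224 adjusted over the 5 shares). Skeletal muscle genes took 0.0026 ± 0.0002% in femur and 0.0042 ± 0.0007% in calvaria, with the same p, but that difference did not pass without frontal library 1, frontal library 4, parietal library 2 or parietal library 4 (exact permutation p = 0.0571 each). Mylpf carried most of it, and the other members took 0.0024 ± 0.0002% and 0.0028 ± 0.0006% (exact permutation p = 0.429). Immediate early and heat shock genes took 1.22 ± 0.0507% in femur and 0.484 ± 0.0593% in calvaria, also at p = 0.0179 by exact permutation. The mitochondrially encoded share, 0.547 ± 0.105% in femur and 0.722 ± 0.218% in calvaria, did not differ beyond the spread (exact permutation p = 0.25), but it was 0.573 ± 0.0997% in frontal and 0.946 ± 0.0651% in parietal bone, with both parietal libraries above every femur library.

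**Figure D2:**
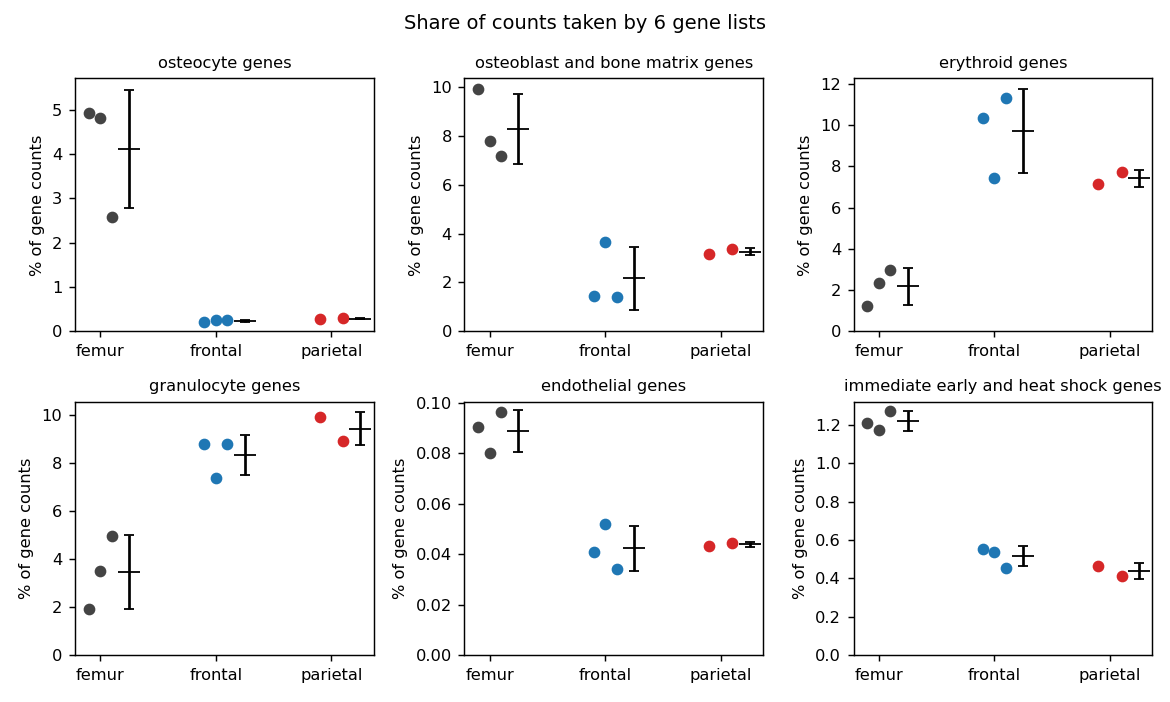
Share of gene counts, in percent, taken by 6 gene lists in each library, with the mean and SD per bone beside the points. Osteocyte and osteoblast genes took more of the femur libraries, erythroid and granulocyte genes more of the calvarial ones.

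Calvaria was first compared with femur. Osteocyte genes were far lower in calvaria. Dmp1, a matrix protein of osteocytes encoded on chromosome 5 (104202613 to 104214102, GRCm38), stood at 528 ± 99.8 CPM in calvaria (SD, n = 5) and 35309 ± 13668 CPM in femur (n = 3), a log2 fold change of -6.04 ± 0.30 (SE, adjusted p = 5.4e-08). Sost, which encodes the Wnt inhibitor sclerostin (chromosome 11, 101962458 to 101967015), fell from 306 ± 114 to 24.2 ± 4.24 CPM, a log2 fold change of -3.69. Phex, an endopeptidase of phosphate balance (chromosome X, 157162075 to 157415312), fell by 3.98, and Mepe, a matrix phosphoglycoprotein (chromosome 5, 104325329 to 104338611), fell by 2.68. Fgf23, the phosphate-lowering hormone (chromosome 6, 127072902 to 127081408), had a log2 fold change of -0.63 ± 0.35 and did not pass (adjusted p = 0.14). Without frontal library 1 it did (-0.92, adjusted p = 0.0133).

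Of the 16 osteocyte genes tested, 12 fell, 2 rose and 2 did not pass, with a median log2 fold change of -2.81 (camera adjusted p = 6.1e-11; adjusted p = 0.0424 with an estimated correlation). Fam20c (-3.76 ± 0.12), Ackr3 (-3.44 ± 0.16) and Pdpn (-5.75 ± 0.28), which encode a matrix kinase, a chemokine receptor and podoplanin, were among those that fell. The 2 that rose, Dstn (0.79) and Capg (0.69), encode actin-binding proteins, and Kcnk2 (0.49, adjusted p = 0.12) did not pass, though it did without femur library 1 (0.79, adjusted p = 0.0231) and with the length and GC trend removed (0.75, adjusted p = 0.0296). These 3 were named after their values were seen, and Dstn no longer passed with that trend removed (0.30, adjusted p = 0.0577). Of 23 osteoblast and bone matrix genes 18 fell, and 19 adjusted over the list alone, among them Sp7 (-2.97), Alpl (-2.61), Col5a1 (-2.24) and Col24a1 (-3.12). The list's median was -1.55 (camera adjusted p = 3.1e-05; adjusted p = 0.376 with an estimated correlation). The 5 that did not pass by edgeR with all libraries, named after their values were seen, were Pth1r (-0.59), Bmp3 (-0.58), Omd (0.30), Ibsp (0.08 ± 0.20) and Ifitm5 (0.09 ± 0.27). The calls of Pth1r and Bmp3 depended on the method. Both passed by limma-voom (adjusted p = 0.039 and 0.0434) and with the replicate block (0.0208 and 0.0408), and Pth1r by DESeq2 (0.0324). Both also did without frontal library 2 (-0.79 and -0.91), and Pth1r without frontal library 4 (-0.47) or parietal library 2 (-0.74). Ibsp, the sialoprotein of mineralizing matrix, stood at 1110 ± 353 CPM in calvaria and 1070 ± 297 CPM in femur. Of 15 phosphate and mineralization genes 14 fell, with Ank at -2.84 (median -2.32; adjusted p = 0.0839 with an estimated correlation). These falls went along with the higher erythroid and granulocyte shares given above.

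**Figure D3:**
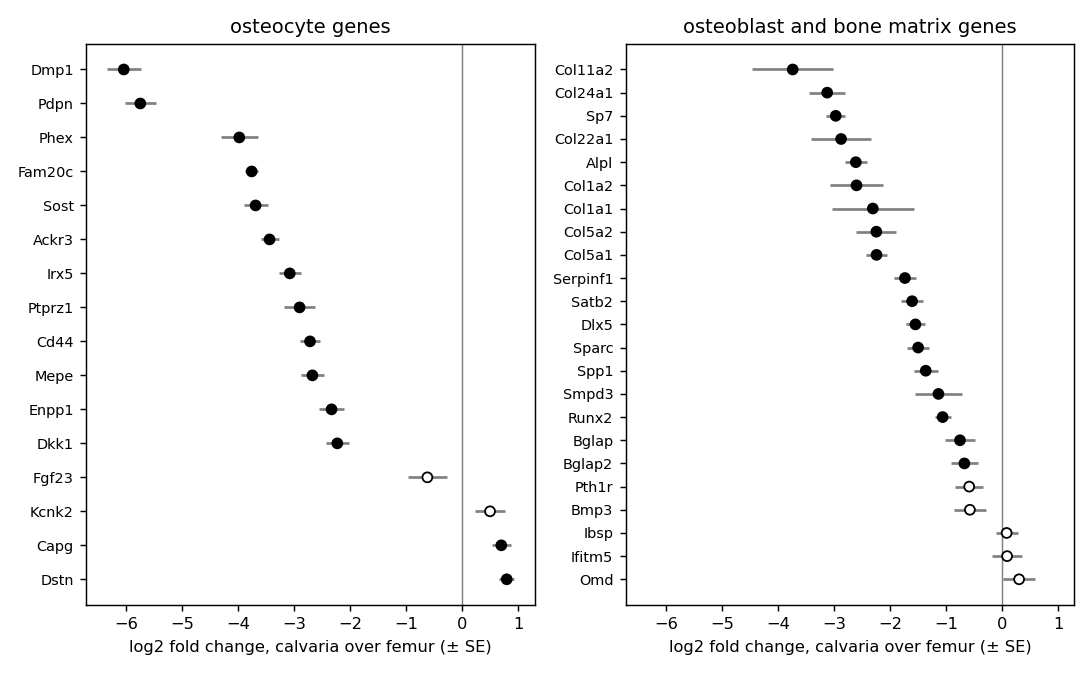
Log2 fold change, calvaria over femur, of each tested osteocyte gene (left) and osteoblast or bone matrix gene (right), on the TMM scale, with bars of 1 SE and filled points for genes past an adjusted p of 0.05. Dmp1 lies at -6.04, while Ibsp and Ifitm5 lie near 0.

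Of 14 osteoclast regulators 9 fell and 2 rose, beside the higher erythroid and granulocyte shares, with Tnfsf11, the osteoclast-inducing ligand RANKL, at -2.34 ± 0.11, Il11 at -7.32 ± 0.39, Il6 at -2.24 and Csf1 at -1.74. Cxcl12 (1.24) and Il34 (1.49) rose, the latter named after its value was seen. The list's median was -1.74 (camera adjusted p = 6.0e-05; adjusted p = 0.0728 with an estimated correlation). Osteoclast genes did not move as a list (camera adjusted p = 0.581). Of 13, 5 rose, such as Ctsk (1.17) and Atp6v0d2 (1.45), and 2 fell, Nfatc1 (-2.75) and Itgb3 (-1.07), the latter no longer past the threshold with the length and GC trend removed (-0.36, adjusted p = 0.123). Perilacunar remodelling genes, which dissolve matrix around osteocytes, also did not pass as a list, with 5 of 13 higher and 6 lower, or 7 lower adjusted over the list alone (camera adjusted p = 0.277).

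Several signalling lists were lower in calvaria at camera's preset correlation, beside the higher erythroid and granulocyte shares, while IGF axis genes did not pass (5 of 13 lower, camera adjusted p = 0.0808). Of 29 Wnt ligands and receptors 23 fell, with Wnt5b at -6.13 ± 0.24, Lgr6 at -5.37, Wnt1 at -4.90 and Fzd7 at -3.06, while Rspo2 (2.91) and Lgr5 (1.19, named after its value was seen) rose. The median was -1.96 (camera adjusted p = 6.1e-11; adjusted p = 0.0504 with an estimated correlation). Of 17 Wnt antagonists 13 fell, and 14 adjusted over the list alone, including Sfrp4 (-2.71), Kremen1 (-2.69) and Dkk1 (-2.23), and Dkkl1 rose (1.81, named after its value was seen). That list passed with an estimated correlation too (adjusted p = 0.0458). Of 37 BMP and TGF-beta ligands, receptors and antagonists 31 fell, with Bmp2 at -4.64, Bmp8a at -5.20, Ltbp1 at -3.69 and Bmp7 at -4.05 (median -1.56; adjusted p = 0.108 with an estimated correlation). Of 13 targets of these pathways 11 fell, among them Smad7 (-2.96), Id3 (-2.18), Id1 (-1.94) and Ccn2 (-1.62), with adjusted p = 0.0424 at an estimated correlation. Of 17 Notch genes 14 fell, and 15 adjusted over the list alone, such as Jag2 (-3.09) and Hes1 (-2.22), with adjusted p = 0.0424 at an estimated correlation. Lfng, named after its value was seen, rose (0.56), but not without femur library 2 (0.40), frontal library 1 (0.53) or parietal library 2 (0.50). Of 15 FGF pathway genes 12 fell, such as Fgfr1 (-3.50), Dusp6 (-2.60), Etv5 (-2.65) and Fgf1 (-7.20; list adjusted p = 0.0613 with an estimated correlation). Of 28 mechanosensing genes 21 fell, with the ion channel Piezo1 at -3.63, the transcriptional co-activator Wwtr1 at -2.93, the gap junction gene Gja1 at -3.21 and the integrin Itga5 at -1.92 (median -1.66; adjusted p = 0.0998 with an estimated correlation). Wnt target genes fell in 10 of 16 cases and rose in 2 (median -1.14; adjusted p = 0.0998 with an estimated correlation).

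Hox genes and most other limb patterning genes tested were lower in calvaria, beside the higher erythroid and granulocyte shares. Of 41 Hox genes and Hox cluster transcripts 8 were expressed enough to test, and all 8 fell in calvaria. Hoxa10 stood at 9.51 ± 1.85 CPM in femur (n = 3) and 0.087 ± 0.054 CPM in calvaria (n = 5). Hoxc10 and Hoxc9 had 2 counts each in all calvarial libraries and were 83.9-fold (95% counting interval 23.2 to 693) and 95.9-fold (26.6 to 792) higher in femur, and Hoxa9 fell by 2.00. Hoxa10, Hoxc10, Hoxc9 and Hoxc6, the last at 0 counts in calvaria, could pass the filter only through femur. For these members only a fall could be seen, and the list's median and p rest in part on them. The median was -5.22, or -4.46 with the member at 0 counts set at its bound (camera adjusted p = 8.2e-05; adjusted p = 0.0502 with an estimated correlation). Of 12 other limb patterning genes 8 fell, or 9 adjusted over the list alone, including Shox2 (-5.25 ± 0.31), Irx3 (-3.76), Irx5 (-3.08) and Tbx15 (-2.43), and 2 rose, among them En1 (3.6 ± 0.48). The list's adjusted p was 0.0504 with an estimated correlation. Of 23 cranial and neural crest genes 4 rose, Alx1 (3.04), Zic1 (3.32), Alx4 (1.33) and Zic4 (2.78), and 13 fell, such as Dlx3 (-4.16) and Foxc2 (-2.92). As a list these moved down (median -0.86; adjusted p = 0.219 with an estimated correlation), and not past the threshold with the length and GC trend removed (adjusted p = 0.0587). En1, Alx1, Zic1, Alx4 and Zic4 were named after their values were seen, and had a mean of 4.45 CPM (Alx4 in parietal bone) or less in every bone. Zic4 passed without frontal library 1, 2 or 4 but not without any 1 of the other libraries (2.22 to 3.43), and by limma-voom neither Alx1 (adjusted p = 0.0614) nor Zic4 (0.10) did. Zic4 also did not with the replicate block (2.64, adjusted p = 0.0658).

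**Figure D4:**
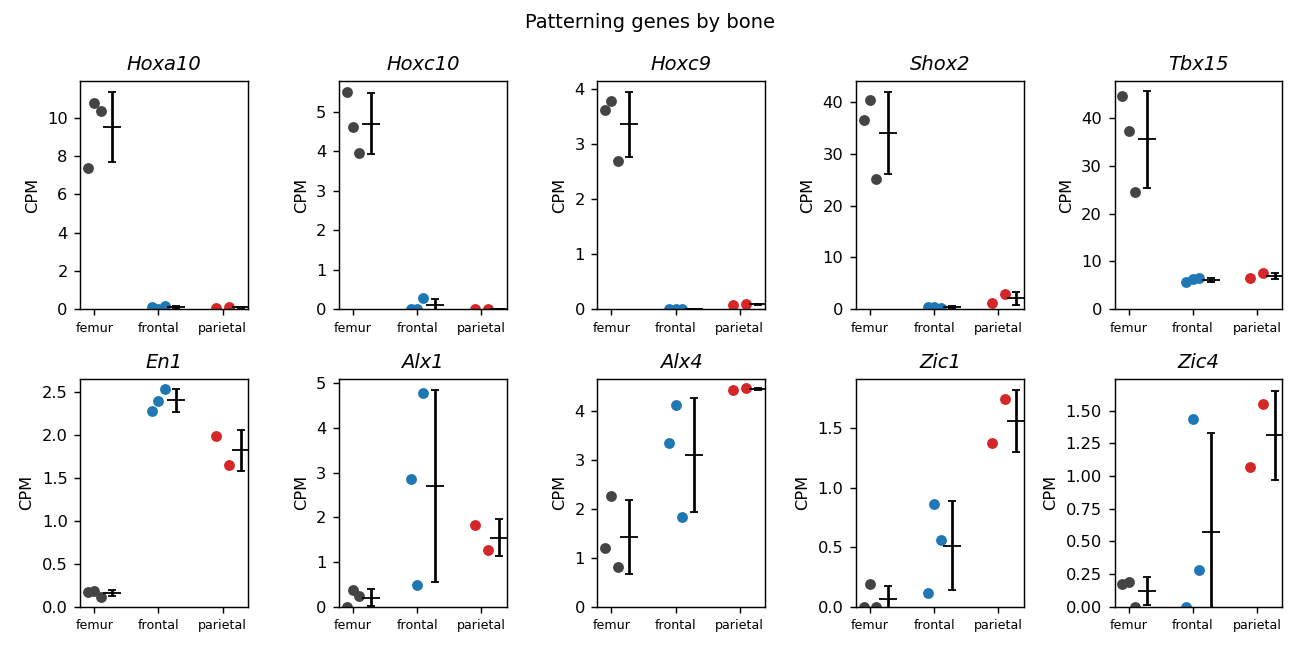
CPM of 10 patterning genes in each library by bone, with the mean and SD per bone beside the points. Hoxa10, Hoxc10, Hoxc9, Shox2 and Tbx15 were higher in femur, and En1, Alx1, Alx4, Zic1 and Zic4 were higher in calvaria, at low levels and with at least 1 frontal library within the femur range for Alx4, Zic1 and Zic4.

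Most lists of blood cell genes were higher in calvaria, while megakaryocyte and platelet genes did not pass as a list (5 of 12 higher, 1 lower, camera adjusted p = 0.317). All 18 erythroid genes tested rose, with Klf1 at 2.05, Hbb-bs at 1.95, Fech at 1.51 and the carbonic anhydrase Car1 at 3.80 ± 0.20 (median 1.54; adjusted p = 0.249 with an estimated correlation). Of 19 granulocyte genes 14 rose, such as Ms4a3 (1.62), Ctsg (1.54), Mcpt8 (1.78) and S100a8 (1.92; list adjusted p = 0.376 with an estimated correlation). Of 15 B cell genes 12 rose, such as Igll1 (2.22), Ms4a1 (2.14) and Cd79b (2.01; list adjusted p = 0.0998 with an estimated correlation). Of 15 T and NK cell genes 10 rose, and 12 adjusted over the list alone, with Klrb1c at 3.22 (list adjusted p = 0.126 with an estimated correlation). Of 17 monocyte and macrophage genes 12 rose, such as Ccr2 (1.48), Ly6c2 (1.74) and Lyz2 (1.79), and 3 fell, Mertk (-1.77) and, named after their values were seen, Vcan (-1.41) and Cd14 (-0.59; list adjusted p = 0.197 with an estimated correlation). All 16 proliferation genes rose, with Ccnb1 at 2.23, Tyms at 2.06 and Cdk1 at 1.93 (median 1.56; adjusted p = 0.138 with an estimated correlation). Of 27 nuclear genes of oxidative phosphorylation 24 rose, such as Ndufb3 (2.02), Cox6c (1.37) and Sdhb (1.45; list adjusted p = 0.130 with an estimated correlation). Endothelial genes went the other way, with 15 of 17 lower, such as Robo4 (-1.81), Flt1 (-1.58), Sox17 (-2.40) and Emcn (-1.35; list adjusted p = 0.198 with an estimated correlation). All 19 immediate early and heat shock genes fell, with Egr1 at -3.01 ± 0.13, Ier3 at -2.72, Fosb at -2.43 and Egr3 at -3.97 (median -1.56; adjusted p = 0.0504 with an estimated correlation).

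In all, 9464 of 15511 genes changed between calvaria and femur by edgeR's quasi-likelihood test, 4596 higher and 4868 lower in calvaria. Beyond the genes named above, the largest rises were in Aldh1a7 (3.71), Tac2 (3.49), Hebp1 (3.35), Pklr (3.11) and Mylpf (3.06). The largest falls were in Neu2, with 1 count in the 5 calvarial libraries and a 1020-fold higher level in femur (95% counting interval 183 to 40200), and in Sprr1a, with 0 counts in calvaria and a level at least 128.9-fold higher in femur. Wnt7b (-7.36), Adamtsl2 (-7.35), Wnt16 (-7.07) and Thbs4 (-6.91) followed. Wnt16 had 0 counts in frontal bone, so its value and rank rest in part on a fitted value there. All directions are relative to the TMM scale, on which the median gene stood at 0.01. With the libraries scaled to the osteocyte list instead, an alternative chosen after seeing the data, the median gene stood at 2.88, 14536 genes were higher and 199 lower in calvaria, and 4422 of the genes called on the TMM scale turned in sign. With the length and GC trend removed, also chosen after seeing the data, 547 did. The osteocyte scale takes the typical osteocyte gene as equal in all libraries. Its shift thus follows from the fall of that list and is no independent check.

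The frontal bone was then compared alone with femur. Dmp1 fell by 6.17, from 35309 ± 13668 CPM in femur to 489 ± 117 CPM in frontal bone (SD, n = 3 each), and the log2 fold changes of Sost, Phex and Mepe were -3.57, -4.54 and -3.03. Fgf23 did not pass (0.36 ± 0.37, adjusted p = 0.43; -0.22 without frontal library 1). Of 16 osteocyte genes 12 fell and 2 rose (median -2.97; adjusted p = 0.0354 with an estimated correlation), and of 23 osteoblast genes 19 fell, or 20 adjusted over the list alone (adjusted p = 0.290 with an estimated correlation). All 18 erythroid genes rose (median 1.88; adjusted p = 0.173 with an estimated correlation), and the frontal libraries had an erythroid share of 9.71 ± 2.04% against 2.19 ± 0.89% in femur. The largest rises were in Tac2 (3.97), Aldh1a7 (3.87), Car1 (3.85), Pklr (3.52), Hebp1 (3.32), Mylpf (3.19), Klrb1c (3.11) and the amino acid transporter Slc6a20a (3.07). Neu2, Sprr1a and Wnt16 had 0 counts in frontal bone and were at least 159-fold, 65.8-fold and 55.3-fold higher in femur. Il11 (-7.94), Thbs4 (-7.74), Fgf1 (-7.20), Dok7 (-6.97) and Adamtsl2 (-6.94) also fell. edgeR called 8639 genes, 4226 higher and 4413 lower in frontal bone, and 30 of 43 lists passed, of which 8 also did with an estimated correlation. Monocyte and macrophage genes did not pass in frontal bone (camera adjusted p = 0.0689), while periosteum, tendon and fibroblast genes did, with 9 of 15 lower (0.0206; adjusted p = 0.296 with an estimated correlation). Without a composition factor (library size only) the median gene moved by 0.134.

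The parietal bone was compared with femur in the same fit. Dmp1 fell by 5.91, to 586 ± 36.4 CPM (SD, n = 2), and the log2 fold changes of Sost, Phex and Mepe were -3.81, -3.42 and -2.32. Fgf23 fell by 1.62 (adjusted p = 0.011). Without parietal library 2, which left 1 parietal library, its log2 fold change was -1.27 and it was no longer called. Of 16 osteocyte genes 13 fell and 2 rose, or 3 adjusted over the list alone (median -2.49; adjusted p = 0.0736 with an estimated correlation). Of 23 osteoblast genes 14 fell and 1 rose (adjusted p = 0.533 with an estimated correlation). Of 13 mitochondrially encoded genes 11 rose (median 0.73; adjusted p = 0.530 with an estimated correlation). With the length and GC trend removed, this list moved down (adjusted p = 0.0212). The erythroid share was 7.42 ± 0.409% in parietal bone, and 16 of 18 erythroid genes rose (adjusted p = 0.371 with an estimated correlation). The largest rises were in Car1 (3.74), Aldh1a7 (3.54), Hebp1 (3.39), Klrb1c (3.32), the Wnt agonist Rspo2 (3.31), Clec4b1 (3.25), Hist1h2an (3.12) and Zfp808 (3.09). Sprr1a had 0 counts in parietal bone and was at least 63.1-fold higher in femur. Neu2 and Wnt7b, with 1 count each, were 395-fold (95% counting interval 70.8 to 15600) and 365-fold (65.5 to 14400) higher in femur, and Foxa3, with 3 counts, 127-fold (43.6 to 618). Adamtsl2 (-7.75), Bmp8b (-7.32), Fgf1 (-7.21) and Il11 (-6.71) fell as well. edgeR called 8633 genes, 4199 higher and 4434 lower in parietal bone, and 29 of 43 lists passed, of which 0 did with an estimated correlation (smallest adjusted p = 0.0608; 13 lists at an unadjusted p under 0.05).

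Frontal and parietal bone were also compared with each other. Of 13 mitochondrially encoded genes 10 were called lower in frontal bone, and 13 adjusted over the list alone, but the list did not pass with an estimated correlation (adjusted p = 0.791) or with the length and GC trend removed (adjusted p = 0.282). mt-Nd1 stood at 731 ± 74.0 CPM (SD, n = 3) in frontal and 1308 ± 70.2 CPM (n = 2) in parietal bone, a log2 fold change of -0.84 ± 0.16 (adjusted p = 0.028), and mt-Co3 (-0.98), mt-Atp6 (-0.96) and mt-Co2 (-0.91) fell too. Of 23 osteoblast and bone matrix genes 5 were lower in frontal bone and 18 did not pass (list adjusted p = 0.791 with an estimated correlation), with Omd at -1.64 ± 0.34, Bglap (osteocalcin) at -1.37, Bglap2 at -1.36, Spp1 at -1.06 and Ifitm5 at -1.29, the last named after its value was seen. None of the 5 was called with the length and GC trend removed. The osteoblast and bone matrix share was 1.46, 3.66 and 1.40% in frontal libraries 1, 2 and 4. It was 3.16 and 3.37% in parietal libraries 2 and 4, so frontal library 2 went the other way. Fgf23 was higher in frontal bone, at 9.13 ± 5.46 against 2.35 ± 0.937 CPM (1.98 ± 0.46, adjusted p = 0.036).

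Sost (0.24), Dmp1 (-0.26), Mepe (-0.71, adjusted p = 0.095) and Phex (-1.12, adjusted p = 0.10) did not pass between the calvarial bones. Of 13 perilacunar remodelling genes 4 fell in frontal bone, and 6 fell and 1 rose adjusted over the list alone, with Tgfbr1 at -1.10, Atp6v0d2 at -1.07, Ctsk at -0.97 and Atp6v1g1 at -0.57. Of 27 nuclear oxidative phosphorylation genes 7 fell, or 12 adjusted over the list alone, such as Cox6c (-0.72), Ndufa2 (-0.57), Cycs (-0.59) and Uqcrc2 (-0.56). Of 17 monocyte and macrophage genes 2 fell, or 7 adjusted over the list alone, Ms4a7 (-0.99) and Ccr2 (-0.81) over all genes. Of 12 marrow stroma and adipocyte genes Fabp4 (-0.96) fell, with 3 adjusted over the list alone. Of 18 erythroid genes Ermap (1.14) rose, with 6 adjusted over the list alone, beside an erythroid share of 9.71 ± 2.04% in frontal and 7.42 ± 0.409% in parietal bone. These 7 lists passed camera at the preset correlation, with adjusted p from 1.4e-10 (mitochondrially encoded) to 0.049 (marrow stroma), and each had adjusted p = 0.791 with an estimated correlation. With the length and GC trend removed 20 lists passed, without the mitochondrially encoded one. Without frontal library 4 there were 4 lists, with the osteoblast (adjusted p = 0.111), perilacunar (0.0745), erythroid (0.0570) and marrow stroma (0.0947) lists not past the threshold, and without frontal library 2 there were 13. The marrow stroma list also did not pass without frontal library 1 (0.115), parietal library 2 (0.0748) or parietal library 4 (0.151), or with DESeq2 size factors (0.0517), and the nuclear oxidative phosphorylation list did not with the libraries scaled to the osteocyte list (0.126).

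Rises in frontal bone were largest in Carmil2 (1.98), Arhgap33 (1.78), Tchp (1.68), Gfi1b (1.67), Slc2a4 (1.58), Kmt2d (1.55) and Clcn2 (1.55), beside Fgf23. Gfi1b is a transcription factor of red cell and platelet precursors, and Kmt2d a histone methyltransferase. The largest falls were in Xlr (-2.52), Rpl39l (-1.94), Kctd12b (-1.80), Dpyd (-1.76), the prostaglandin receptor Ptgfr (-1.74), Pik3r3 (-1.73), Abca8a (-1.71) and Frk (-1.67). edgeR called 1118 genes, 607 higher and 511 lower in frontal bone, with a smallest adjusted p of 0.027. The count fell to 0 with the replicate block, and likewise without femur library 2, frontal library 1, parietal library 2 or parietal library 4 by edgeR, with 2520 to 4059 genes at an unadjusted p under 0.05, and to 518 without frontal library 4, and rose to 1963 without frontal library 2 and to 1714 without femur library 1. With all libraries DESeq2 called 2225 genes and limma-voom 1579. With a trend in transcript length and GC content removed, 63 genes were called, and of the 37 named genes called here 4 (Gfi1b, Kmt2d, Abca8a and Cox6c) were.

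**Figure D5:**
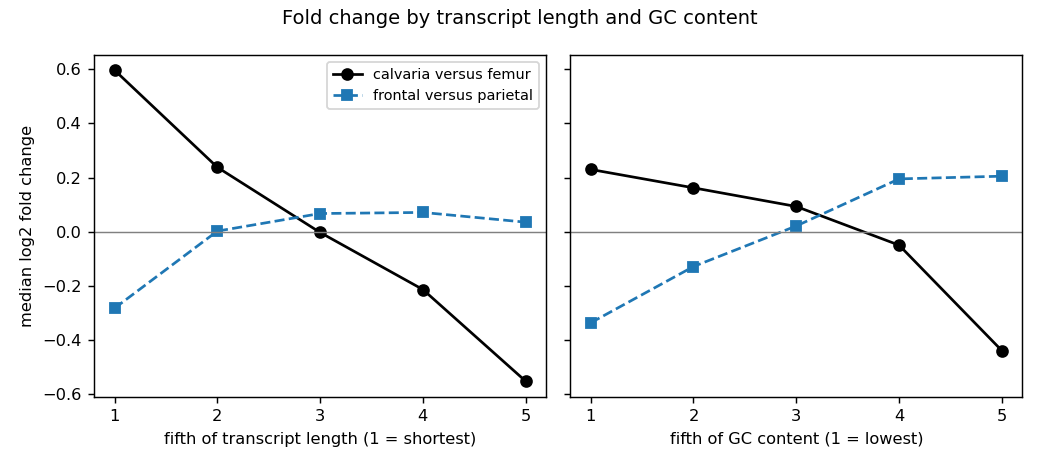
Median log2 fold change of tested genes in 5 equal groups by transcript length (left) and by GC content (right), for calvaria over femur (circles) and frontal over parietal (squares). From the shortest to the longest group the median ran from 0.60 to -0.55 in calvaria over femur, and from the lowest to the highest GC group from -0.34 to 0.21 in frontal over parietal.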

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

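The tests of explanations, of the endothelial share and of other splits were chosen only after the result was seen, while the tests of frontal against parietal and of the erythroid and immediate early shares were fixed earlier.

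In 143 values compared over the 5 calvarial libraries, which span 2 bones, 9 had 1 library far from the others, where chance marks about 5% of them. Dmp1 stood at 355 CPM in frontal library 1 against 547 to 611 CPM in the others, and Dkkl1 at 4.30 CPM there against 2.33 to 2.77 CPM. Frontal library 2 was highest for Col5a1 (62.1 CPM, others 34.8 to 39.7), Jag1 (11.5 CPM, others 6.99 to 8.03), Hoxa9 (2.39 CPM, others 1.16 to 1.43) and Irx5 (8.32 CPM, others 4.35 to 5.14). Frontal library 4 held the only counts of Hoxc10 (0.281 CPM), and parietal library 4 the only count of Neu2 (0.097 CPM) and the highest Il11 (1.07 CPM, others 0.14 to 0.359).

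Among the genes named for frontal or parietal bone against femur, the difference from femur itself differed between these bones for 3. The test was the direct one of frontal against parietal, which 37 of the 41 genes named for that comparison passed. Fgf23 had log2 fold changes of 0.36 in frontal and -1.62 in parietal bone, a difference of 1.98 (edgeR adjusted p = 0.0361). Slc6a20a had 3.07 and 1.96, a difference of 1.11 (adjusted p = 0.0378), and Tac2 3.97 and 3.01, a difference of 0.96 (adjusted p = 0.0463). All 3 calls rest on the comparison whose count of calls fell to 0 with the replicate block, and likewise without femur library 2, frontal library 1, parietal library 2 or parietal library 4 (edgeR; 2520 to 4059 genes at an unadjusted p under 0.05).

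Spike-in RNA, used in no comparison, took from 0.0286% of counts (femur library 2) to 0.176% (frontal library 1).

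Osteocyte genes were lower in calvaria while blood cell genes were higher. If fewer osteocytes had only made room for all other cells alike, every other cell type should have risen, but the endothelial share changed by -1.06 on the log2 scale (exact permutation p = 0.0179) while the erythroid share rose by 2.08. If blood cells had diluted all bone cells by 1 factor, Sost, Dmp1, Mepe, Phex and Fgf23 should have fallen alike, but their log2 fold changes spanned 5.42, with a largest SE of 0.349. With the length and GC trend removed the list median was -2.49 (before, -2.81), so that trend was not the whole cause. Camera then gave an adjusted p of 2.8e-13 at the preset correlation and 0.049 with an estimated one. A mixture of more marrow cells with a different state or kind of bone cell may explain the rest and was not tested, and the difference between the bones themselves cannot be parted from how each bone's fraction was isolated.

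Immediate early and heat shock genes were lower in all 5 calvarial libraries. Removing the length and GC trend left the list median at -1.42 (before, -1.56), which goes against that trend as the whole cause. The camera adjusted p was then 2.2e-11 at the preset correlation and 0.049 with an estimated one. The lowest femur share exceeded the highest calvarial share by 0.626 percentage points (1.18 and 0.551%). This gap cannot part bone from handling before lysis, since the labels give no handling times and an overlap would not have parted them either. The calvarial libraries also had higher erythroid and granulocyte shares, and their part in this fall was not tested.

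Frontal and parietal bone differed in 1118 genes. The length and GC trend is a candidate explanation for part of these differences. Once it was removed, 58 of the 1118 genes were still called (63 genes in all) and 14 turned in sign. Such a trend also varied between libraries of 1 bone. The Spearman correlation of log2 differences with GC content was 0.322 between frontal libraries 1 and 4, against 0.362 for frontal over parietal. In the other pairs of 1 bone it ran from -0.161 to 0.149. With transcript length it ran from -0.182 to 0.196 within a bone, against 0.166. The median size of the log2 fold change of the called genes went from 0.80 to 0.60 and their median SE from 0.183 to 0.179, but these genes were chosen for being called, with adjusted p of 0.027 at the smallest. With the trend removed 3295 genes had an unadjusted p under 0.05 (4460 before), so part of the drop may reflect calls close to the threshold, which was not tested. A different share of marrow cells could also contribute. The erythroid median exceeded the monocyte and macrophage median by 0.94, which a common rise of blood cells would not give, but the erythroid list alone had a fry p of 0.217 (monocyte list 0.00326), so it cannot be told apart from the spread between libraries.

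With the 8 libraries in 2 groups, 8530 genes changed between calvaria and femur by edgeR. The highest of the other 55 splits into 5 and 3 libraries gave 0 (30 to 4476 genes at an unadjusted p under 0.05). The real split was therefore 1 of 56 with as many, a share of 0.0179 that takes the libraries as exchangeable. Each of the other splits put femur and calvarial libraries together in at least 1 group, which widens the spread. Their counts of 0 were thus likely beforehand, and chance is not excluded by them. If the numbers paired the libraries, the splits within numbers would be too few for a share under 0.05. For frontal against femur the real split, 1 of 10, gave 8639 genes and the highest other gave 0 (104 to 456 at an unadjusted p under 0.05). Those splits are too few for a share under 0.05.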

How the results depend on the processing

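Scaling to the osteocyte list, the 2-group fit, leaving out the lists of other cell types removing the length and GC trend and leaving out the list member that differs most were chosen after seeing the data. The 3 counts against femur stayed within 1.5 times under all alternatives but 2. Scaled to the osteocyte list they were 14735, 14671 and 14246 (calvaria, frontal, parietal), and with a 2-fold change also required 5321, 5060 and 5717. Totals hide changes in which genes are called: with the length and GC trend removed 7159 of 9464, 6803 of 8639 and 6076 of 8633 calls were kept, and 547, 272 and 552 turned in sign. Leaving out 1 library gave 8260 to 9467, 7483 to 8366 and 6615 to 8841 genes. Frontal against parietal depended on the processing. It gave 1904 genes without a filter on low counts, 2225 with DESeq2 (adjusted p NA for 3613; limma-voom 1579), 63 with the length and GC trend removed, 269 with a 2-fold change required and 0 at an adjusted p under 0.01, and 0 to 1963 without 1 library. The counts of 0 had 2520 to 4460 genes at an unadjusted p under 0.05. Calvaria against femur used all libraries, so fitting only those compared gave nothing new. Without 1 parietal library, the other is assumed to vary like the other bones. By library size only, 75.6% of its calls were higher in frontal bone against 54.3% by TMM; scaled to the osteocyte list, 96.7% of 1303 were, against 98.6% to 98.9% in the femur comparisons. Except where stated, the cause was not tested.

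With the replicate block, frontal against parietal gave 0 genes (3504 at an unadjusted p under 0.05), and the femur comparisons 8912, 8163 and 7693. Deviations from the bone's mean of libraries with the same number correlated at -0.082, -0.103 and 0.022 (femur with frontal), -0.048 and -0.059 (femur with parietal) and 0.057 and 0.145 (frontal with parietal). Those with different numbers ran from -0.145 to 0.172. The 2 parietal libraries deviate from their mean by opposite amounts, so values with them come in pairs of opposite sign. The -0.145 (frontal 4 with parietal 2) is thus the 0.145 of frontal 4 with parietal 4, turned in sign. For this reason, and with so few libraries, these values cannot decide whether the numbers paired the libraries.

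With a correlation estimated per list, 6, 8, 0 and 0 lists passed (calvaria, frontal and parietal against femur, frontal against parietal), against 30, 30, 29 and 7. Without 1 library these were 29 to 31, 30 to 31, 28 to 30 and 4 to 13. With the length and GC trend removed, 20 lists passed in frontal against parietal, and the mitochondrially encoded list turned from higher to lower in parietal against femur (adjusted p = 0.0212). Log2 differences of shares without 1 library ran from 0.236 to 0.512 (mitochondrial), 1.70 to 2.35 (erythroid), 1.07 to 1.76 (granulocyte), 0.607 to 0.77 (muscle, with exact p = 0.0571 without frontal 1, frontal 4, parietal 2 or parietal 4) and -1.39 to -1.28 (immediate early). With the list member that differs most left out they were 0.341, 2.02, 1.28, 0.154 (exact p = 0.429) and -1.23, so the muscle difference rested on Mylpf. Over the 1000 genes of highest variance, library correlations were 0.933, 0.612 and 0.902 (within a bone, femur with calvaria, frontal with parietal).

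Scaled to the osteocyte list, 39 of 129 named genes past the threshold turned in sign in calvaria against femur, 1 of 20 in frontal and 2 of 21 in parietal bone against femur, and 0 of 37 in frontal against parietal. Under the other alternatives run for named genes, those that turned in sign had not passed. Without 1 library Ibsp ranged up to 0.31, Ifitm5 to 0.37 and Fgf23 in frontal bone to 0.66. Ibsp turned to -0.03, -0.04 and -0.04 without femur 2, femur 4 and frontal 2, and to -0.38 with the trend removed, Ifitm5 to -0.19, -0.08 and -0.17 without femur 4, without frontal 2 and with the trend removed, Omd to -0.33 with the trend removed, and, in frontal bone, Fgf23 to -0.22 without frontal 1. At this depth, with 200 genes changed in the simulation, 54.6% of simulated 2-fold changes were recovered in calvaria against femur and 45.4% in frontal against parietal. Recovery in the real data, where far more genes were called, may differ.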

Other observations

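Further groups fixed in advance differed between calvaria and femur. Of 16 circadian clock genes 13 were lower in calvaria, with the repressor Nr1d1 at -3.66 ± 0.17, Cry2 at -2.34, Cry1 at -2.05 and Bhlhe40 at -2.04, and Per3 was higher (1.06, named after its value was seen; adjusted p = 0.0547 without parietal library 4; list adjusted p = 0.0424 with an estimated correlation). Of 17 hypoxia and glycolysis genes 12 were lower, such as Vegfa (-3.91 ± 0.20), Adm (-3.45), Ndrg1 (-2.74) and Slc2a1 (-1.50), and Car9 was higher (1.47, named after its value was seen; list adjusted p = 0.0424 with an estimated correlation). Both groups were lower beside the higher erythroid and granulocyte shares of the calvarial libraries, and a link between them was not tested.

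Neurite, hedgehog, cartilage and smooth muscle genes were lower beside the higher erythroid and granulocyte shares of the calvarial libraries. Of 37 neurite and axon guidance genes 27 were lower in calvaria, or 28 adjusted over the list alone, such as Nrp2 (-2.79; list adjusted p = 0.130 with an estimated correlation). Of 10 hedgehog pathway genes 8 were lower, such as Boc (-3.37) and Ihh (-3.61; list adjusted p = 0.0998 with an estimated correlation). Of 14 cartilage genes 8 were lower, with Sox9 at -1.98 and Chad at -5.19, and Col2a1, named after its value was seen, stood at 557 ± 290 CPM in femur and 6.37 ± 3.86 CPM in calvaria (list adjusted p = 0.216 with an estimated correlation, and 0.0582 at the preset one without femur library 1). Interferon response genes did not move as a list (4 of 19 higher, 8 lower, camera adjusted p = 0.875). Of 9 smooth muscle and pericyte genes 6 were lower (median -1.50; adjusted p = 0.145 with an estimated correlation). That list did not pass at the preset correlation without femur library 1 or 4, frontal library 1 or 4, or parietal library 4 (adjusted p from 0.0503 to 0.0636), or with the length and GC trend removed (0.0865).

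The other lists did not pass by camera in calvaria against femur. Their adjusted p was 0.0642 for periosteum, tendon and fibroblast genes, 0.0808 for IGF axis genes, 0.118 for Schwann cell genes and 0.158 for mitochondrially encoded genes. It was 0.285 for meningeal, 0.317 for megakaryocyte, 0.336 for hormone receptor, 0.486 for skeletal muscle, 0.581 for brain and 0.788 for marrow stroma and adipocyte genes.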
